A study of Mus musculus with 2 samples.

How the data were processed

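Total RNA from the mouse mammary carcinoma line 4T1 was profiled in 2 libraries, 1 from control-treated cells and 1 from cells treated with LY500307, a synthetic agonist of estrogen receptor beta. Per the labels' protocols, RNA was extracted with TRIzol, depleted of ribosomal RNA and made into stranded total RNA libraries with a TruSeq kit. The submitters' processing notes name CASAVA 1.8, Bowtie2 and the mouse build mm9, without saying what each was used for. The read counter, the gene annotation, the treatment of reads with several matches, the use of strand and the normalization tool are not given in the sources used here. The dose and duration of treatment are likewise not given in them.

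The deposited table holds 1 value per library for 19498 Ensembl mouse genes. The deposited values are a signal per gene in the form of read counts rescaled to a common library size, per the file's own values rather than any stated method. Each column is a series of whole multiples of a single step, 1.03059 in the control-treated library and 0.970322 in the LY500307-treated library. After division by the step, 99.95% and 99.96% of values lay within 0.01 of a whole number, and the largest deviations were 0.0329 and 0.0342. These whole numbers are called recovered reads. They summed to 14541874 in the control-treated and 15104003 in the LY500307-treated library. Relative to those totals, the deposited scaling lowered the treated values against the control values by a further factor of 1.02, or 0.03 on the log2 scale. Every listed gene had at least 2 recovered reads over both libraries, so genes below that were not analysed here. A value of 1.39e-17 in the table was read as 0. Symbols were taken from GENCODE M21 by Ensembl ID, and 19443 of the 19498 IDs matched. Among the IDs, 2120 are numbered above 100000, and the annotation behind the table could not be tied to a build, so no coordinates are given.

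The group of each column came from the sample labels. The comparison was the log2 ratio of the LY500307-treated to the control-treated deposited value after a pseudocount of 1.03 was added to both. This scale understates the difference of genes with few reads. The pseudocount is the 5th percentile of all values above 0. Genes were kept where the higher of their values reached a floor of 33.0, the 40th percentile of values above 0, and genes at least 2-fold apart on that scale were counted. These percentiles had been set before the data were examined for tables in a unit other than counts or FPKM. The alternative written for count tables was applied to the recovered reads as an added setting. With 1 library per group there is no replicate check of any difference, so no p-value, standard error or count of significant genes is given. No count-based test was fitted to the recovered reads, because 1 library per group leaves no residual degrees of freedom. The fold of a single gene is the ratio of its deposited values without a pseudocount. Its 95% interval is the exact Clopper-Pearson interval of the treated share of its recovered reads, rescaled to a fold. Intervals cover counting error only, since 1 library per group gives no spread between cultures. They treat each read as independent. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for counting error.

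Before the data were examined, 41 gene lists with 950 symbols were written for pathways, cell types and controls. The list of neutrophil chemoattractants and granulopoietic cytokines was written with knowledge of the study's published topic, interleukin 1 beta and neutrophils. Each list with at least 5 members at or above the floor was described by its median log2 ratio and by the percentile of that median among 10000 random lists of equal size, drawn from 20 bins of mean expression with seed 1. A list below the 2.5th or above the 97.5th percentile is said to stand apart, as a description of these libraries. Members at least 1.5-fold higher or lower on the log2 scale were counted.

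Genes were named by a rule set before the data were examined. It took the 12 highest and 12 lowest log2 ratios among genes whose higher value reached 295.8, the 60th percentile of values above 0, leaving out gene models without a proper name. It also took up to 4 members of each list that stood apart, in the direction of the median, and each measured member of the neutrophil list with Esr1 and Esr2. Members named for other lists and genes named in the closing observations were chosen after their values were seen.

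After the data were seen, a trend of the log2 ratio in transcript GC content and length was fitted by robust regression on cubic splines with 5 degrees of freedom each, over nuclear genes at or above the floor. GC contents and lengths outside the central range of these genes were moved to its ends for the fit and the removal. GC content and length came from the longest GENCODE M21 transcript of each gene and were known for 99.9% of genes at or above the floor. Other settings tried were a pseudocount of 1, no floor, a floor of 50 reads, median-centred ratios, upper-quartile scaling, a 1.5-fold threshold and the mean over list members. CPM of recovered reads with a pseudocount of 0.5 and a floor of 10 reads, protein-coding genes only, removal of the GC and length trend and omission of mitochondrial genes were added after the data were seen.

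The calculations were tested on simulated data for this comparison, with reads drawn for all 19498 genes and 11330 at or above the floor. Noise between the simulated libraries beyond counting had an SD of 0.15 on the log2 scale for every gene. It was chosen rather than estimated, as there are no replicates, and the simulated reads carried no GC trend. The shares that follow check the calculation and are not rates of false calls in the data. Of 67 genes simulated at 2.5-fold, 95.5% passed the 2-fold threshold, as did 100% of 66 genes at 4-fold, 1.49% of 67 genes at 1.5-fold and 0.108% of 11130 genes without a difference. Among 100 random lists of 20 genes, 3% stood apart, and all of 20 lists shifted by 0.2 on the log2 scale did. A GC trend imposed on the simulated ratios, with a Spearman correlation of −0.68, was reduced to 0.00 by the fit. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, patsy 1.0.2 and matplotlib 3.10.9 were used.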

Results

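Gene expression was measured by ribosomal RNA-depleted RNA sequencing in 4T1, a metastatic mouse mammary carcinoma line, with 1 control-treated and 1 LY500307-treated library. The study asked which RNAs differ between 4T1 cells treated with LY500307, an estrogen receptor beta agonist, and control-treated cells. Recovered reads numbered 14541874 in the control-treated and 15104003 in the LY500307-treated library. Eef1a1, a translation elongation factor, had the most reads in both, and the 10 genes with the most reads held 5.18% and 5.15% of the total. Pseudogenes held 2.53% and 2.41% of reads, and genes of the mitochondrial genome 1.82% and 2.25%. There are no replicates, so every difference below describes these 2 libraries.

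Transcripts of neutrophil-attracting chemokines and of interleukin 1 were higher in the LY500307 library, and most measured targets of ATF4, the transcription factor of the integrated stress response, were lower. Il1b (ENSMUSG00000027398), which encodes the inflammatory cytokine interleukin 1 beta, was 2.42-fold higher, with 21 reads in the control-treated and 54 in the LY500307-treated library (95% counting interval 1.44 to 4.22). The chemokine gene Cxcl3 was 1.61-fold higher (1.35 to 1.92). Trib3, a pseudokinase gene that ATF4 controls, was 1.70-fold lower (1.56 to 1.87). The largest log2 ratio of either sign at or above the floor was that of mt-Nd3, which encodes a subunit of respiratory complex I and was 5.48-fold higher (4.75 to 6.36).

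Differences of 2-fold or more were few. Of 11384 genes at or above the floor, 47 were at least 2-fold higher in the LY500307 library and 25 at least 2-fold lower. The median log2 ratio was −0.02, with quartiles at −0.18 and 0.13 and the 5th and 95th percentiles at −0.44 and 0.38. Across genes, which are not independent replicates, the log2 values of both libraries had a Pearson correlation of 0.991 and a Spearman correlation of 0.993. Among 3536 genes with at least 2000 reads over both libraries, the SD of the log2 ratio across genes was 0.18, against 0.05 expected from counting. Protein-coding genes made up 92.0% of genes at or above the floor but 31 of the 47 genes that were 2-fold higher and 9 of the 25 that were lower. Pseudogenes, whose reads can be shared with their parent genes, made up 4.63% of genes at or above the floor, 8 of the 47 and 10 of the 25. The counting intervals excluded 1 for all 47 and all 25 genes, which had been selected for their size. They also excluded 1 for 41.8% of all genes at or above the floor, 2060 higher and 2699 lower. An interval that excludes 1 therefore does not by itself set a gene apart. With a floor of 50 reads the counts of 2-fold genes were 19 and 10, and with CPM of recovered reads and the count-table floor 105 and 44.

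**Figure D1:**
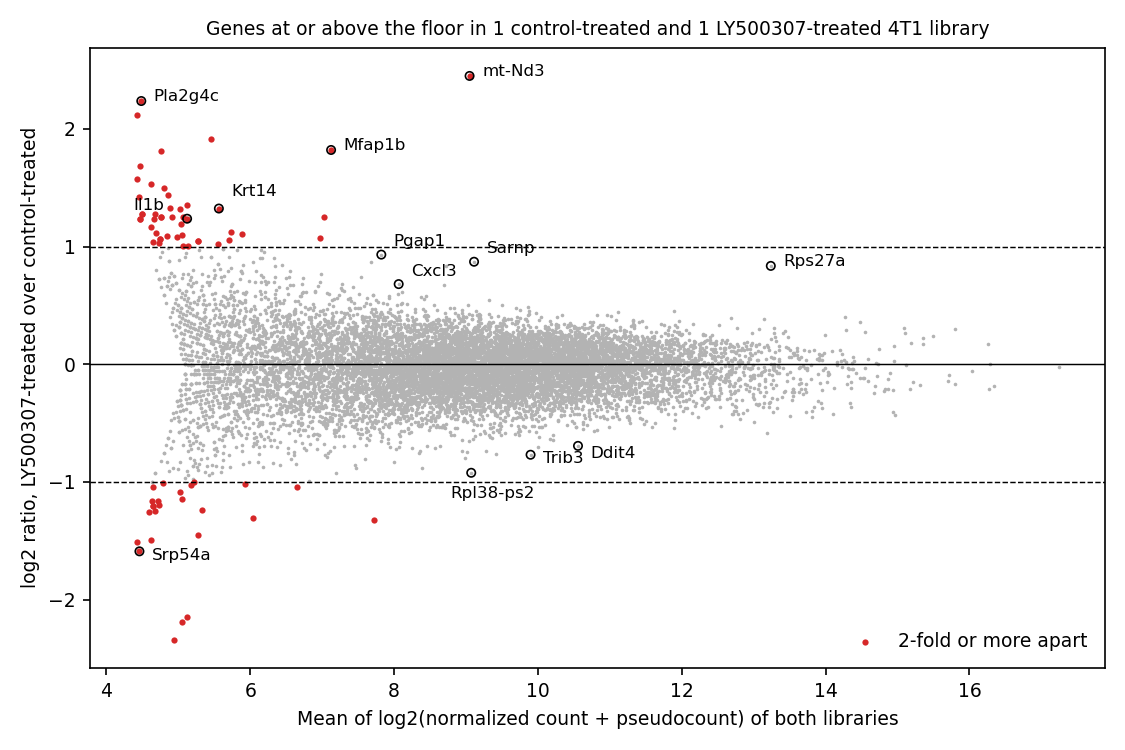
Each point is 1 of 11384 genes, with the mean of log2(normalized count + pseudocount) of both libraries on the x axis and the log2 ratio of the LY500307-treated over the control-treated library on the y axis. Dashed lines mark 2-fold, red points are the 47 genes above and 25 genes below them, most of them at low levels, and circled genes are named.

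The list of neutrophil chemoattractants and granulopoietic cytokines stood apart as higher, with a median log2 ratio of 0.21 at percentile 99.8 of random lists. Of its 10 members at or above the floor, 3 were at least 1.5-fold higher, none were 1.5-fold lower, and 7 lay above 0. Beside Il1b and Cxcl3, the third was Ppbp, another CXC chemokine gene, with 53 and 92 reads (1.63-fold higher, 1.15 to 2.34). Cxcl5, the most abundant chemokine transcript of the list, had 1734 and 2452 reads and was 1.33-fold higher (1.25 to 1.42). Il1a, which encodes interleukin 1 alpha, was 1.18-fold higher (1.06 to 1.31), the complement gene C3 1.14-fold (1.03 to 1.26) and Cxcl1 1.09-fold (1.02 to 1.17). Not all growth factors of the myeloid lineage followed. Csf3, which encodes the granulocyte growth factor G-CSF, was 1.21-fold lower (1.12 to 1.31), and Lif was 1.14-fold lower (1.04 to 1.24). Csf1 stood at 0.979 of the control value (0.927 to 1.03). After removal of a GC and length trend, described below, the log2 ratio of Csf3 went from −0.27 to −0.076 and that of Lif from −0.19 to −0.11, while that of Cxcl3 went from 0.68 to 0.56, that of Cxcl5 from 0.41 to 0.27, that of Il1a from 0.24 to 0.093 and that of Cxcl1 from 0.12 to 0.038. With Cxcl3 below 1.5-fold, 2 members were then 1.5-fold higher, and 8 lay above 0.

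Several members of the list lay below the floor. Csf2, which encodes GM-CSF, had 16 and 33 reads, a fold of 1.94 (1.04 to 3.78). Cxcl2 had 7 and 13 reads, Pf4 1 and 5, S100a8 4 and 6, S100a9 1 and 1, and Il6 4 and 0, and at this depth no difference was detectable for these 5 genes. Esr1, which encodes estrogen receptor alpha, had 47 and 72 reads (fold 1.44, 0.985 to 2.13). Esr2, which encodes estrogen receptor beta, the receptor that LY500307 activates, had 6 and 4 reads (fold 0.628, 0.130 to 2.65). Neither receptor differed beyond counting error.

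**Figure D2:**
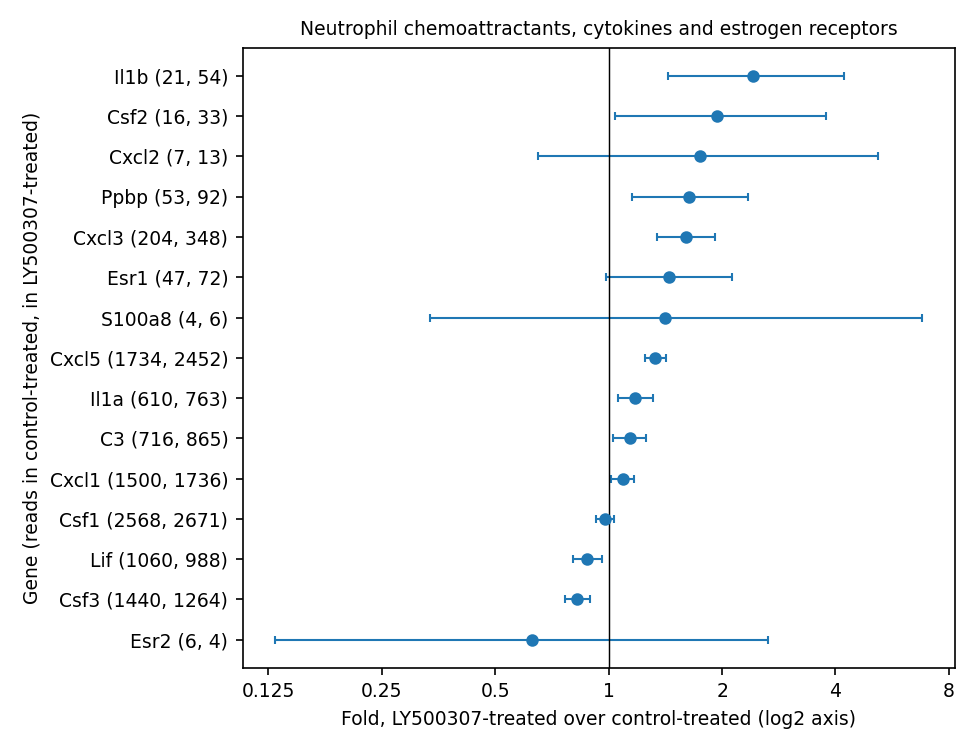
Points show the fold of the LY500307-treated over the control-treated library on a log2 axis for members of the neutrophil list, Esr1 and Esr2 with at least 10 reads over both libraries, and bars show exact 95% counting intervals. Recovered reads of both libraries stand beside each gene, and the interval of Il1b, 1.44 to 4.22, lies wholly above 1 while that of Esr2, 0.130 to 2.65, spans it.

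Targets of ATF4 and the integrated stress response stood apart as lower, with a median of −0.25 at percentile 0. Of 31 measured members, 29 lay below 0, and 4 were at least 1.5-fold lower. These were Trib3, with 1207 and 752 reads, Cebpb, which encodes a bZIP transcription factor (1.69-fold lower, 1.52 to 1.89), Ddit4, an inhibitor of mTORC1 signalling, with 1858 and 1220 reads (0.618 of the control value, 0.575 to 0.665), and Chac1, a glutathione-degrading enzyme, with 733 and 518 (0.665, 0.593 to 0.746). The exceptions above 0 were Atf3, with 198 and 215 reads, and Cebpg, with 602 and 677. After removal of the trend 29 members again lay below 0, but none was 1.5-fold lower, with log2 ratios of −0.53 for Trib3, −0.46 for Ddit4, −0.38 for Cebpb and −0.37 for Chac1. The related unfolded protein response did not stand apart on the deposited values, with a median of 0.03, but after removal of the trend it stood apart as higher, with 0.050.

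Immediate early genes, which respond rapidly to growth factors and stress, stood apart as lower with a median of −0.20. Of 25 measured members, 14 lay below 0 and 1 was 1.5-fold lower. Ier2 was 1.52-fold lower (1.40 to 1.65), the AP-1 subunit gene Junb 1.45-fold (1.38 to 1.53), the phosphatase gene Dusp5 1.42-fold (1.32 to 1.52) and Zfp36, which encodes an mRNA-destabilising protein, 1.40-fold (1.15 to 1.70). Classical estrogen-responsive genes had a median of −0.22, with 10 of 15 members below 0 and none 1.5-fold apart. Krt19 was 1.28-fold lower (1.19 to 1.38), Stc2 1.26-fold (1.05 to 1.52), Rara 1.24-fold (1.09 to 1.41) and Igfbp4 1.23-fold (1.19 to 1.27). After removal of the GC and length trend, neither list stood apart, with medians of −0.06 for immediate early and −0.07 for estrogen-responsive genes. Log2 ratios were then −0.28 for Ier2, −0.16 for Junb, −0.31 for Dusp5, −0.13 for Krt19, −0.047 for Rara and −0.17 for Igfbp4. Those of Zfp36 and Stc2 went from −0.48 and −0.34 to −0.36 and −0.32, within their counting intervals. No immediate early gene was then 1.5-fold lower and 1 was 1.5-fold higher. The estrogen-responsive list also no longer stood apart without a floor, with the mean over members or with CPM of recovered reads. The CPM setting also lowered the floor, so that 17 members were measured. Median-centring shifts a list and its random lists alike, so it could not change the percentile of 0.26.

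Cytosolic ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower by small amounts. Of 48 ribosomal protein genes, 39 lay below 0, with a median of −0.15. Rps28 was 1.38-fold lower (1.34 to 1.43), Rps29 1.34-fold (1.30 to 1.39), Rpl18 1.32-fold (1.29 to 1.36) and Rpl35 1.32-fold (1.28 to 1.37). Of 37 nuclear oxidative phosphorylation genes, 28 lay below 0, with a median of −0.10. Cox6a1 was 1.46-fold lower (1.39 to 1.52), Atp5d 1.32-fold (1.26 to 1.37), Cox5b 1.28-fold (1.20 to 1.36) and Uqcrq 1.26-fold (1.18 to 1.34). No member of either list was 1.5-fold apart on the deposited values. After removal of the trend the medians were −0.066 for ribosomal protein genes, of which 1, Rps2, was then 1.5-fold higher, and −0.077 for oxidative phosphorylation. The log2 ratios of Rpl35, Cox6a1 and Atp5d went from −0.40, −0.54 and −0.40 to −0.18, −0.12 and −0.12. Those of Rps29 and Rpl18 went from −0.42 and −0.41 to −0.31 and −0.32. Rps28, Cox5b and Uqcrq changed little, from −0.47, −0.35 and −0.33 to −0.46, −0.32 and −0.30. Ribosomal protein genes have many pseudogene copies, so their reads are uncertain.

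The protein-coding genes of the mitochondrial genome were higher, 13 of 13 above 0, with a median of 0.30. Beside mt-Nd3, with 219 and 1275 reads, mt-Nd4 was 1.32-fold higher (1.29 to 1.35), mt-Nd6 1.31-fold (1.27 to 1.36) and mt-Atp6 1.26-fold (1.17 to 1.35). No gene of this list other than mt-Nd3 was 1.5-fold apart, and after removal of the trend the median was 0.16, with log2 ratios of 0.20 for mt-Nd4, 0.25 for mt-Nd6 and 0.16 for mt-Atp6.

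Targets of the aryl hydrocarbon receptor and xenobiotic metabolism had the highest median, 0.39, over 6 members, 5 of them above 0, of which Ahr and Arnt encode the receptor and its partner rather than targets. Cyp1b1, an oxidase of estrogens and xenobiotics, was 1.68-fold higher (1.36 to 2.08) with 138 and 246 reads. Ahr, the receptor gene itself, was 1.47-fold higher (1.16 to 1.88), Tiparp 1.26-fold (1.18 to 1.35) and Aldh3a1 1.37-fold, with an interval that spans 1 (0.985 to 1.91). Nqo1 stood at 0.984 of the control value (0.771 to 1.26), and below the floor the target gene Ahrr had 16 and 8 reads (0.471, 0.174 to 1.17) and Cyp1a1 0 and 2. Heat shock genes had a median of 0.13, with 14 of 18 above 0. Hspa4l was 1.34-fold higher (1.25 to 1.43), Hsf2 1.25-fold (1.09 to 1.43), the mitochondrial chaperonin gene Hspd1 1.22-fold (1.20 to 1.25) and Hsp90aa1 1.20-fold (1.18 to 1.22). Genes of G2/M and mitosis had a median of 0.07, with 22 of 32 above 0. Hmmr was 1.36-fold higher (1.28 to 1.45), Cenpf 1.21-fold (1.15 to 1.26), Bub1 1.18-fold (1.10 to 1.27) and Cenpe 1.16-fold (1.11 to 1.22). No member of the heat shock or mitosis list was 1.5-fold apart. After removal of the trend the log2 ratio of Tiparp went from 0.33 to 0.16. The heat shock median was then 0.060, with 0.18 for Hspa4l, 0.091 for Hsf2 and 0.16 for Hsp90aa1, and the mitosis median was 0.020 with 19 of 32 above 0, with log2 ratios of 0.083 for Cenpf, 0.090 for Bub1 and 0.041 for Cenpe.

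In all, 5 of the 34 lists tested stood apart as higher and 5 as lower, where 1.7 lists of random genes matched on expression would. That number is no measure of evidence, because members of a list can vary together and some lists share genes. The lists also differ in GC content, with medians of 37.1% for mitochondrially encoded and 55.5% for immediate early genes, and the random lists were not matched on it. The other 24 lists did not stand apart. Among these, the interleukin 1 pathway and inflammasome list, which shares Il1a and Il1b with the neutrophil list, had a median of 0.04, NF-kB targets −0.05, the interferon response 0.01 and MHC class I antigen presentation −0.09. Estrogen receptors and coregulators had a median of 0.09, epithelial and keratin genes −0.09, mesenchymal genes 0.05, TGF-beta targets −0.07, YAP/TEAD targets −0.02, angiogenesis −0.01 and metastasis-associated proteases −0.01. Medians were −0.03 for G1/S and DNA replication, 0.01 for apoptosis regulators, −0.01 for p53 targets, −0.02 for the NRF2 response, −0.06 for hypoxia and glycolysis, −0.01 for autophagy and lysosome and −0.04 for the circadian clock. Cholesterol biosynthesis had a median of −0.12, fatty acid synthesis −0.06, LXR targets −0.26 over 6 genes, abundant non-coding RNAs 0.09 and housekeeping genes −0.04.

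**Figure D3:**
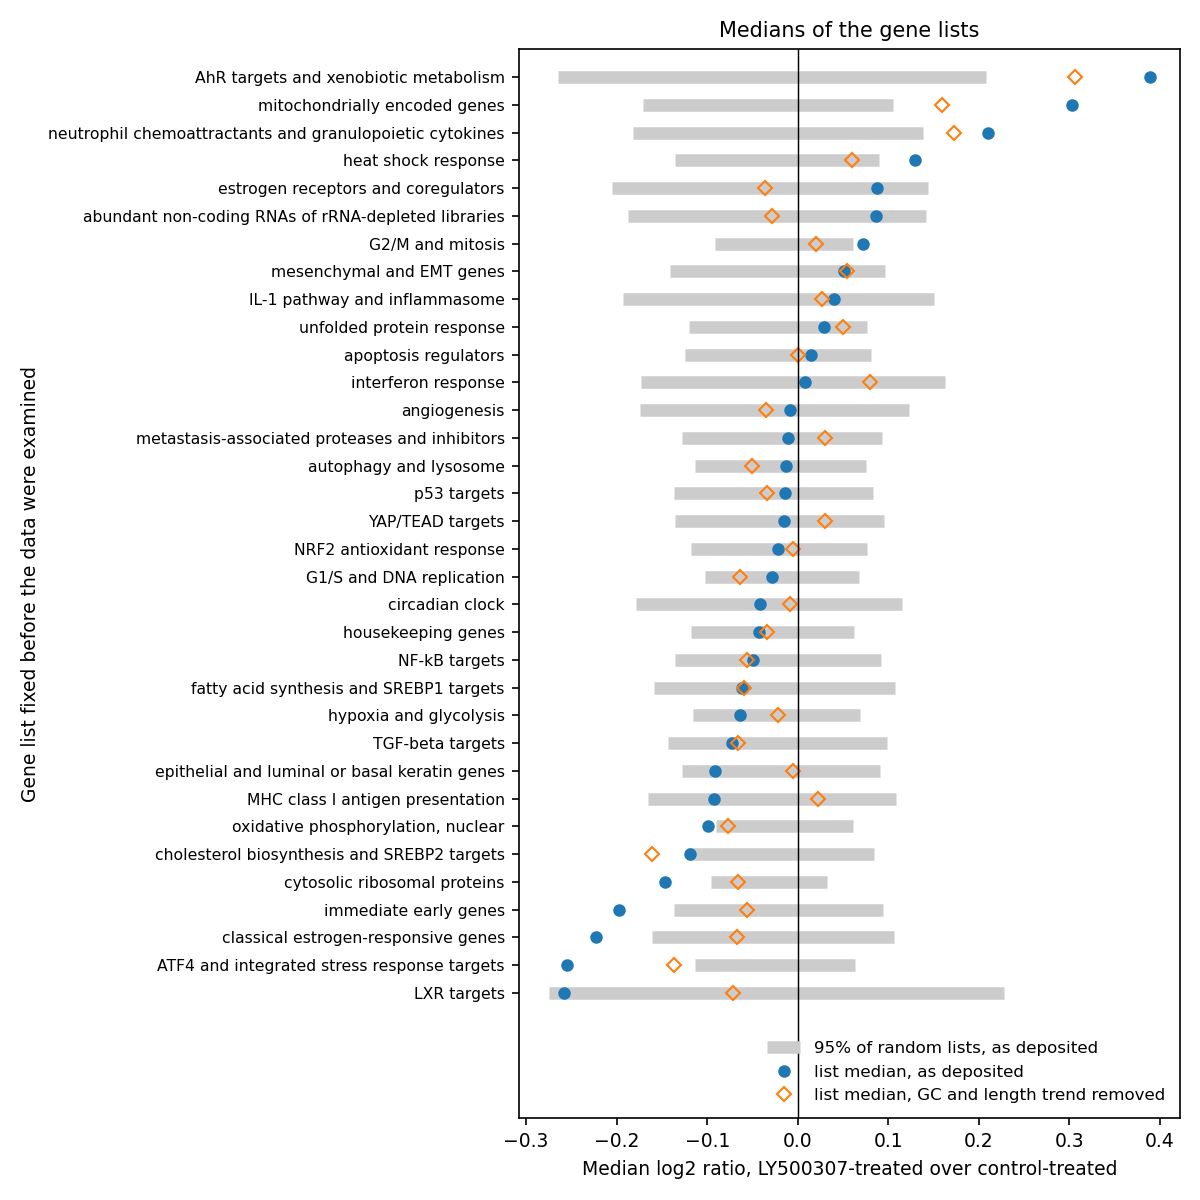
Filled points give the median log2 ratio of each of the 34 lists, grey bars the central 95% of matched random lists on the deposited values, and open diamonds the median after removal of the GC and length trend. The neutrophil list stays at 0.17 and the ATF4 list at −0.14 after removal, while the immediate early list goes to −0.06.

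Markers of other cell types were scarce. Myeloid markers had 4 members at or above the floor, Cd68, Cd14, Cd74 and Mrc1, and their folds, 1.19, 1.11, 1.08 and 0.812, all had counting intervals that span 1. Beside the higher neutrophil list, the leucocyte gene Ptprc had 2 and 4 reads and the myeloid lysozyme gene Lyz2 8 and 2. Endothelial markers had 4 members at or above the floor, fibroblast markers 3, other chemokines 3 and replication-dependent histones 3, too few for a median, and lymphoid markers and erythroid and hepatocyte markers had 0.

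The 12 largest ratios among genes that reached a value of 295.8 included, after mt-Nd3, Pgap1, an enzyme that remodels GPI anchors (1.91-fold higher, 1.58 to 2.33), Sarnp, a nuclear RNA-binding protein gene (1.83-fold, 1.62 to 2.07), and Rps27a, which encodes a fusion of ubiquitin and a ribosomal protein (1.78-fold, 1.73 to 1.84, with 7019 and 13304 reads). Together with its copy Rps27a-ps2 it was 1.72-fold higher (1.68 to 1.77), and reads shared with other copies remain uncertain. The others, with Cxcl3, were Lcorl, Zfp617, the mitochondrial tRNA gene mt-Tp, Cep290, Rufy2, Xpnpep3 and Ift74, at 1.43-fold to 1.52-fold. The 12 smallest ratios included Trib3, Cebpb, Ier5l (1.69-fold lower), Scand1 (1.68-fold), Pgp (1.67-fold), Pex6 (1.67-fold), Rap1gap (1.66-fold), Socs3, a feedback inhibitor of cytokine signalling (1.64-fold, 1.39 to 1.94), and Mvd, an enzyme of cholesterol synthesis (1.63-fold, 1.37 to 1.94). The pseudogenes Rpl38-ps2 (1.90-fold) and Gstp-ps (1.65-fold) and the histone gene Hist1h2ap (1.74-fold) completed them and are uncertain, since near-identical copies can share their reads.

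The log2 ratio followed the GC content of the transcript across genes, with a Spearman correlation of −0.59, and its length, with 0.24. Over nuclear genes at or above the floor, the decile with the lowest GC content had a median of 0.18 and the decile with the highest −0.29. Cebpb, Ier5l, Scand1, Pex6 and Junb are GC-rich, and their log2 ratios after removal of the trend were −0.38, −0.39, −0.34, −0.37 and −0.16. Those of Rap1gap, Socs3, Mvd and Hist1h2ap were then −0.48, −0.46, −0.44 and −0.36, and those of Lcorl and Cep290 went from 0.60 and 0.57 to 0.33 and 0.32. Trib3 went from −0.77 to −0.53, and the values were 1.19 for Il1b, 0.56 for Cxcl3 and 2.32 for mt-Nd3.

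**Figure D4:**
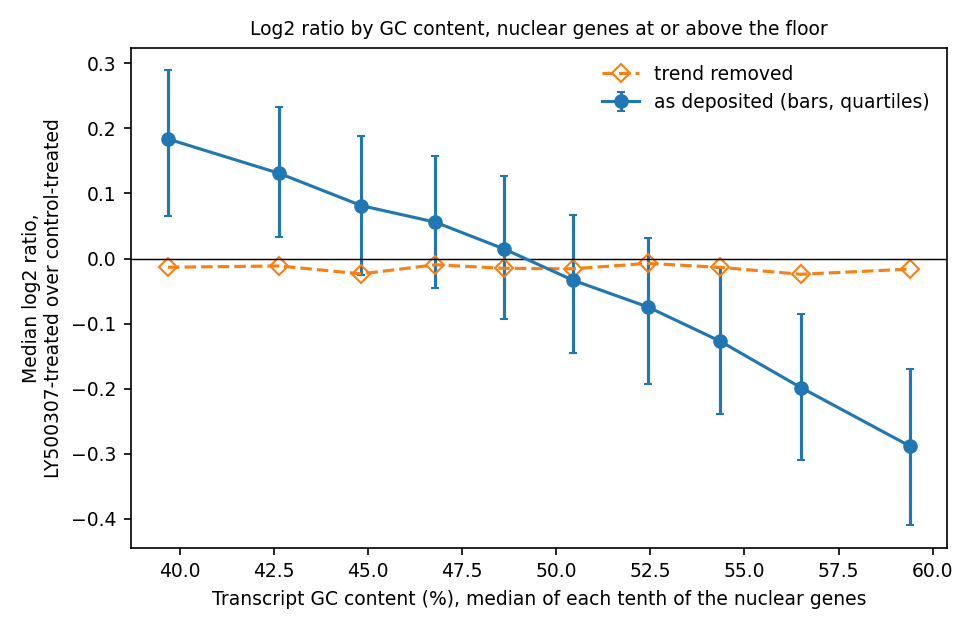
Points show the median log2 ratio of the LY500307-treated over the control-treated library in each decile of nuclear genes by transcript GC content in percent, bars its quartiles, and open diamonds the median after removal of the trend. The median goes from 0.18 in the lowest decile to −0.29 in the highest.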

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

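The settings called added here were chosen after the data were seen. The counts of 47 higher and 25 lower genes became 1671 and 1348 without a floor, 19 and 10 with a floor of 50 reads and 205 and 224 at 1.5-fold. Among added settings they became 105 and 44 with CPM of recovered reads, of which 30 and 10 were among the first 47 and 25, and 31 and 9 with protein-coding genes only. The CPM setting changed the scaling, the pseudocount and the floor together, so its differences here and below cannot be credited to the scaling alone. A pseudocount of 1, both other scalings, removal of the GC and length trend and omission of mitochondrial genes left both counts within 1.5 times. A pseudocount of 1 hardly differs from the main 1.03, so it could change little here and below. With the trend removed the counts were 46 and 20, of which 36 and 18 were among the first 47 and 25. The estrogen-responsive list no longer stood apart without a floor (−0.046), with the mean over members (−0.13), with CPM of recovered reads (−0.050) and with the trend removed (−0.067), and the immediate early list with the trend removed (−0.056). The other 8 lists stood apart in the same direction under each setting run for lists. Median-centring and a pseudocount of 1 were no real test of this. The first cannot change a percentile, and the second hardly differs from the main pseudocount. Lists that came to stand apart were epithelial genes and replication-dependent histones, the latter with too few members at first, without a floor and with CPM of recovered reads, cholesterol biosynthesis with the mean and with the trend removed, the unfolded protein response with the trend removed and LXR targets with protein-coding genes only. The interquartile range of the log2 ratios, 0.31, was 0.48 without a floor, 0.34 with CPM of recovered reads and 0.21 with the trend removed, and the median was 0.021 with CPM of recovered reads. Fewer or more genes enter at another floor, and otherwise the cause was not tested. Of 74 named genes, 41 moved outside their counting interval when the trend was removed, none past 0 where the interval excluded 1. None moved with a pseudocount of 1, an outcome set in advance by its closeness to 1.03. A comparison by the authors was not run because the table holds no folds or p-values. No paired analysis was possible because each group has 1 library and the groups share a single replicate number, and no library could be left out. Depth limits genes near the floor, such as Il1b, whose interval spans 1.44 to 4.22.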

Other observations

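The epithelial, inflammasome, NF-kB, cholesterol, zinc finger and copied genes named here were chosen after their values were seen. So were the tests of myeloid cells as the source of the whole gain, of differences between cultures, of the trend as the whole cause, of a common mitochondrial difference and of short genes without pseudogenes, while the other tests were set before their results were seen.

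The list of epithelial and keratin genes had a median of −0.09, with 13 of 22 members below 0, but some single genes picked by their values were higher from low levels. Krt14, a basal keratin gene, had 28 and 76 reads (2.56-fold, 1.64 to 4.09), Krt87 19 and 52, Sbsn, an epidermal secreted protein gene, 16 and 42, and the epithelial transcription factor gene Ovol1 33 and 70 (log2 ratio 0.98). Its paralog Ovol2 went the other way, with 37 and 17 reads (fold 0.433, 0.228 to 0.788). The phospholipase genes Pla2g4c, with 9 and 49 reads (5.13-fold, 2.49 to 11.9), and Plcd4, with 9 and 45 (log2 ratio 2.12), were the highest protein-coding nuclear genes at or above the floor. The interleukin 1 and inflammasome list did not stand apart, and of its members below the floor 2 had intervals above 1, Nlrp3 with 4 and 15 reads (3.53-fold, 1.12 to 14.6) and Casp4 with 16 and 33 (1.94-fold, 1.04 to 3.78), while Casp1, with 25 and 28 reads, Aim2, with 9 and 11, and Il18, with 12 and 11, did not.

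The NF-kB list, with a median near 0, held members on both sides. Nfkbia, which encodes an inhibitor of NF-kB, stood at 0.733 of the control value (0.669 to 0.803) and Relb at 0.726 (0.627 to 0.840), while Ptgs2, the inducible cyclooxygenase gene, was 1.27-fold higher (1.21 to 1.33) and Birc3 1.40-fold (1.08 to 1.84). Bbc3, which encodes the pro-apoptotic protein PUMA, stood at 0.524 (0.410 to 0.667). The transcription factor genes Snai1 (0.681, 0.551 to 0.840) and Twist1 (0.688, 0.603 to 0.784) were lower, and Tgfb2 was 1.52-fold higher (1.10 to 2.12). With the GC and length trend removed, the log2 ratios of Bbc3, Snai1, Twist1, Relb and Ptgs2 were −0.55, −0.26, −0.26, −0.27 and 0.15. Of 24 cholesterol biosynthesis genes, 21 lay below 0, and with the trend removed 23 did, with a median of −0.16 at percentile 0.

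Some near-identical copies differed from each other, in 6 families looked at because a member stood out. Mfap1b had 71 and 269 reads (3.57-fold higher, 2.74 to 4.70) and its copy Mfap1a 297 and 248 (0.786, 0.662 to 0.934), so that their sum was 1.32-fold higher (1.15 to 1.52). Srp54a had 36 and 12 reads, Srp54b 139 and 71, and Srp54c 225 and 246, and their sum stood at 0.774 (0.667 to 0.898). Rpl38 (0.784) and Rpl38-ps2 (0.527) were both lower, but with the trend removed the log2 ratio of Rpl38 went from −0.35 to −0.019. Gapdh, a glycolytic enzyme gene with many pseudogene copies, had 341 and 398 reads, far fewer than Pfkl, with 9650 and 8491. Among 285 protein-coding zinc finger genes, 176 lay above 0, with a median of 0.09 that became 0.04 with the trend removed.

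The neutrophil list was higher, and a hypothesis is that LY500307 raised these transcripts in 4T1 cells. Esr2, which encodes the receptor that LY500307 activates, had only 6 and 4 reads, and a role of that receptor was not tested. With the GC and length trend removed the median of the list kept 0.17 of 0.21, at percentile 99.96, which met the limits set beforehand. This argues against the trend as the whole cause. That median lies between Il1a, which went from 0.24 to 0.093, and C3, which went from 0.19 to 0.25. How much of the difference goes with the trend therefore cannot be told apart. More myeloid cells in the treated culture cannot be told apart, because 8 leucocyte markers had only 14 and 11 reads, a pooled fold of 0.740 (0.304 to 1.75), and the upper bound missed the limit of 1.5 set beforehand. The test of such cells as the source of the whole gain covered the 7 members at or above the floor with intervals above 1. Of all 11384 genes, 2060 had such intervals. The 7 were chosen by their values, which leaves out the lower Csf3 and Lif. They gained 1137 normalized counts, while 5 abundant transcripts of such cells could reach at most 20.3 in the treated library. S100a8 and S100a9, among the 5, also belong to the list. This argues against such cells as the source of the gain of the 7, if they hold at least as much of the 5 transcripts. Cxcl5, which went from 1787 to 2379 normalized counts, held the largest part of that gain. For Il1b the comparison does not decide, because its gain of 30.8 is near the limit of 20.3. A difference between cultures unrelated to LY500307 cannot be told apart from the treatment with 1 library per group.

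Among the lower lists, the trend in GC content is a candidate explanation for the immediate early genes, whose median went from −0.20 to −0.056, inside the range of random lists. For the ATF4 list the median went from −0.25 to −0.14 and stayed at percentile 0, which argues against the trend as the whole cause. It kept 53.6% of its size and so missed the 67 percent set beforehand, and how much of it goes with the trend cannot be told apart. What produced the trend was not tested, and a difference in library preparation or in the cells may underlie it. An effect of LY500307 on ATF4 targets stays open as a hypothesis.

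The 12 protein-coding mitochondrial genes other than mt-Nd3 had a median of 0.30, which went to 0.15 with the trend removed and stayed at percentile 100. This cannot judge the trend as the whole cause. GC contents beyond the central range of nuclear genes were given the trend at the end of that range. Protein-coding mitochondrial genes had 31.9% to 41.1% GC, against a median of 39.7% in the lowest nuclear decile. The median log2 ratio kept 48.3% and missed the same limit, so the part that goes with the trend cannot be told apart. mt-Nd3 lay 28.4 SDs of those genes above their mean, which argues against a rise shared equally by the protein-coding mitochondrial genes as its source. It was picked as the largest ratio and the limit was written afterwards, so the number of SDs measures no rarity. That SD also leaves out the mitochondrial tRNA genes, which at or above the floor ranged from 0.20 to 1.08 in log2 ratio. More short inserts in the treated library could raise a transcript as short as that of mt-Nd3. The 112 nuclear genes of at most 400 nt had a median of −0.19 (upper bound −0.10) and the 27 that are not pseudogenes −0.10 (upper bound 0.40). This met the limit set beforehand and argues against a rise of short nuclear genes as a set. However, 85 of the 112 are pseudogenes, whose reads can come from longer parent genes. Another 13 are snoRNA genes, with a median of −0.007 and a range of −0.65 to 1.33. All 6 mitochondrial tRNA genes at or above the floor had log2 ratios above 0, with a median of 0.48. Of these, mt-Te and mt-Tw, with 28 and 20 control reads, reached the floor only in the LY500307 library. Such entry favours values above 0. For mt-Nd3 short inserts therefore cannot be told apart. The shorter mitochondrial genes at or above the floor ranged from mt-Atp8, 1.11-fold (0.779 to 1.60), and mt-Nd4l, 1.18-fold (0.968 to 1.44), to the tRNA gene mt-Tn, 2.12-fold (1.63 to 2.78), with intervals above 1 for 3 of 6 tRNA genes, and a difference between the cultures and an effect of LY500307 were not tested.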
